A study of Mus musculus with 21 samples.

How the data were processed

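Gene expression was measured in the livers of 21 male CBA/J mice, each on its own Affymetrix Mouse Genome 430 2.0 array. The mice came from 3 diets, with 7 arrays per diet. Per the labels, liver RNA was extracted with Trizol, and 5 µg of total RNA per mouse was converted to biotin-labelled cRNA. The submitters' processing notes name GCOS 1.2 as the software that computed the signal.

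The deposited table held linear signal intensity per probe set, as made by the authors, for 45101 probe sets. The values ranged from 0.13 to 195329. Detection calls were not used here. The 2% trimmed mean of every array lay between 500 and 500.01, so the deposited scaling was kept. Signals under a floor of 1 (567 of 947121 values, 0.06%) were set to it, and log2 of the deposited intensity was used from there on. No pair of arrays held identical values.

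Of the 45101 probe sets, 64 were array controls. Among the other 45037, 34945 named a single gene, 932 named several and 9160 named none. The gene names came from the platform's probe table, and 34741 of the probe sets with a single gene matched the RefSeq gene table of assembly GRCm38.p6, which was used for names and for a gene's span on the genome. Probe sets were kept when their mean log2 signal over all arrays reached the 50th percentile, 6.43, which corresponds to a signal of 86. Each gene was represented by its brightest kept probe set, which left 11245 of the 18194 named genes. All 22519 kept probe sets were also tested by themselves.

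The 3 diets were compared in one linear model per gene with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3, with 18 residual degrees of freedom. Tests were two-sided, and p was adjusted within each comparison by the Benjamini-Hochberg method at a threshold of 0.05. Fold changes are log2 differences with the standard error (SE) of the model, over 7 mice per diet. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Beside it stood camera with the correlation estimated per list, camera on ranks, and fry. Of 46 lists, 45 were tested, since the list of T cell and NK cell markers had no measured member. Calls within a list were also counted when adjusted over the list alone.

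The lists, the tests, the filter, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and the 8 largest falls among genes past the threshold. With fewer than 16 such genes it took the 5 smallest p in each direction. It also took up to 4 members of each list by p, any list member past the threshold, and 24 fixed genes of lipid and glucose metabolism, of which 18 were measured. The other 6 were not analysed here.

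Signals of the array's own controls were read from its control probe sets. The ratios of middle or 5′ to 3′ signal of pyruvate carboxylase, beta-actin and glyceraldehyde-3-phosphate dehydrogenase were compared between diets by exact permutation tests, two-sided, adjusted over the 45 tests of that family. They were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

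The alternatives were an offset of 50 before log2, quantile scaling, median centring, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, and every probe set by itself. Others changed the model: a fit of the 2 diets compared, the replicate number as a block, array weights, no trend, a robust trend, and each mouse left out in turn. Added after the data were seen were fits with a control ratio as a covariate and fits without fish oil mouse 5, alone or with krill oil mouse 7.

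The procedure was tested on simulated data with 11245 genes and the same spread. For fish oil against control it recovered 23.9% of genes shifted by 0.5 on the log2 scale, 70.1% of those shifted by 1 and 93.9% of those shifted by 2. For krill oil against control it recovered 17.9%, 73.1% and 93.9%, and for krill oil against fish oil 17.9%, 73.1% and 97%. A list shifted as a whole was called in each of the 3 comparisons, and no other list was. The simulated genes were drawn independently, so this does not test list calls for genes that move together. In the real lists the median estimated correlation was 0.138. At the preset correlation, other splits of the real arrays called a median of 9 lists for fish oil against control. They called 6 for krill oil against control and 8 for krill oil against fish oil. The number of arrays limits the precision: the median SE of a log2 fold change was 0.198.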

Results

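The series addressed whether 2 sources of long-chain omega-3 fatty acids, krill oil and fish oil, have different effects on gene expression in the mouse liver. Male CBA/J mice were bought at 6 weeks of age, housed singly and fed from 2 months of age at 84 kcal per week. The control diet, AIN93M, held 4% soybean oil as its fat. The fish oil diet held 1.1% fish oil, and the krill oil diet held 1.5% krill oil. These amounts gave a similar share of eicosapentaenoic plus docosahexaenoic acid, 0.31% of the fish oil diet and 0.29% of the krill oil diet. Each diet was fed to 10 mice, and 7 livers per diet were measured on 1 array each. The labels do not state how long the diets were fed.

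Signals were scaled alike on all arrays, but the shape of their distribution differed between diets. The 75th percentile of signal was 393 ± 24.7 (SD, n = 7) in control, 389 ± 5.6 in fish oil and 324 ± 32.7 in krill oil. The array holds control probe sets along the length of single transcripts, and the ratio of their signals falls when the labelled RNA covers less of the 5′ part. For pyruvate carboxylase, the middle-to-3′ ratio was 0.221 ± 0.0571 (SD, n = 7) in control, 0.145 ± 0.0567 in fish oil and 0.0293 ± 0.014 in krill oil. The krill oil arrays lay below the control arrays (exact permutation p = 0.000583, adjusted 0.00752 over 45 tests) and below the fish oil arrays (exact permutation p = 0.00291, adjusted 0.0119). The fish oil arrays also lay below the control arrays (exact permutation p = 0.0216, adjusted 0.0463), and without fish oil mouse 5 the exact permutation p was 0.0472 (adjusted 0.0817). The beta-actin 5′-to-3′ ratio was 0.483 ± 0.056 in control and 0.36 ± 0.0527 in krill oil (exact permutation p = 0.00117, adjusted 0.00752). In fish oil it was 0.453 ± 0.0766, and krill oil against fish oil did not pass with all arrays (exact permutation p = 0.0268, adjusted 0.0548) and passed without fish oil mouse 5 (0.36 against 0.481, exact permutation p = 0.00117, adjusted 0.00752). The 5′-to-3′ ratio of glyceraldehyde-3-phosphate dehydrogenase was 1.24 ± 0.0733 in control, 1.18 ± 0.0918 in fish oil and 1.15 ± 0.189 in krill oil, and no comparison passed (adjusted exact permutation p = 0.343 for krill oil against control, 0.763 for krill oil against fish oil and 0.281 for fish oil against control). The poly-A spikes, added to the total RNA, had a mean log2 signal of 10.87 ± 0.352 in control, 11.04 ± 1.21 in fish oil and 11.51 ± 0.442 in krill oil. They were brighter in krill oil than in control (exact permutation p = 0.0146, adjusted 0.0346) and than in fish oil without mouse 5 (exact permutation p = 0.00466, adjusted 0.014), but did not pass against all fish oil arrays (exact permutation p = 0.388, adjusted 0.499). Taken relative to the hybridisation spikes, the poly-A spikes did not pass in krill oil against control (exact permutation p = 0.0361, adjusted 0.0677) or against fish oil without mouse 5 (exact permutation p = 0.193, adjusted 0.291). Fish oil mouse 5 stood apart from the other 6 fish oil arrays, with a middle-to-3′ pyruvate carboxylase ratio of 0.025 and a beta-actin ratio of 0.285. Its 5′-to-3′ ratio of pyruvate carboxylase, 0.0864, lay near those of its diet mates (0.0906 to 0.127). On that ratio the krill oil arrays ran from 0.0236 to 0.099 and the control arrays from 0.0938 to 0.2225. The first principal component, which held 44.7% of the variance, placed fish oil mouse 5 at 69.6. The krill oil arrays averaged 80.7 ± 20.3 on that component, and the other 6 fish oil arrays -52.3 ± 8.72.

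**Figure D1:**
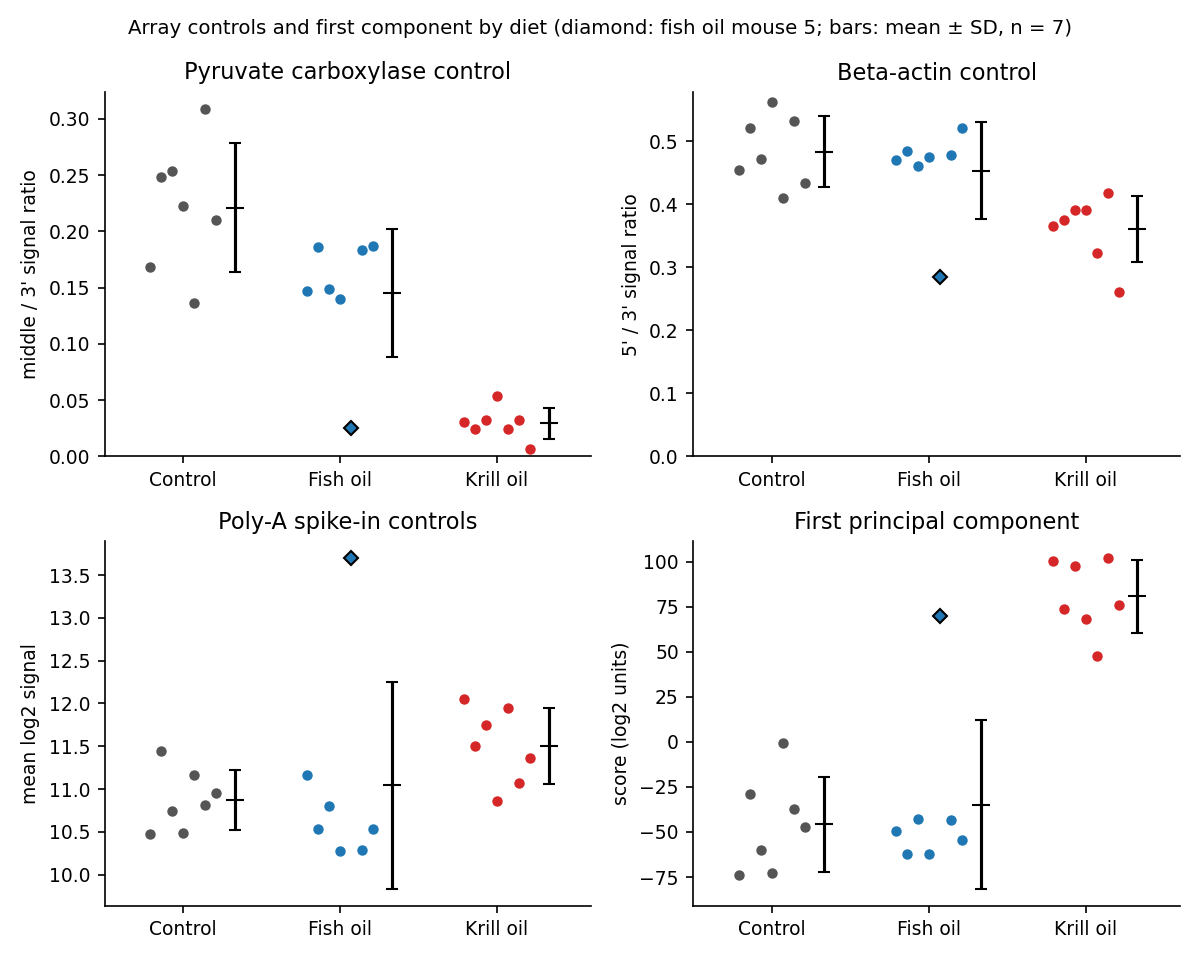
Array controls per array and diet: the pyruvate carboxylase middle-to-3′ and beta-actin 5′-to-3′ signal ratios, the mean log2 signal of the poly-A spike-in controls and the score on the first principal component. Points are arrays, the diamond is fish oil mouse 5 and bars show the mean ± SD of 7 arrays; the krill oil arrays and fish oil mouse 5 have the lowest pyruvate carboxylase ratios, at or below 0.0538.

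Fish oil was compared with the control diet to ask what fish oil did to gene expression in the liver. Genes switched on by PPAR-alpha, the nuclear receptor that senses fatty acids, were higher as a group: 20 of 22 measured targets had a positive fold change, with a median of 0.34. Genes of peroxisomal fatty acid oxidation were also higher (16 of 19 positive, median 0.16), and genes of fatty acid synthesis were lower (14 of 15 negative, median -0.24), but not called without fish oil mouse 5 (median -0.11, adjusted p = 0.0801). All 3 lists passed at camera's preset correlation and not with an estimated correlation (adjusted p = 0.269, 0.269 and 0.567). Among single genes the PPAR-alpha target Cyp4a14, a fatty acid omega-hydroxylase, had a log2 fold change of 1.13 ± 0.45 (SE, 7 mice per diet). Pklr, the liver pyruvate kinase that feeds glycolytic carbon into lipid synthesis, had one of -1.03 ± 0.25. None of the 11245 genes passed the threshold.

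With limma, 0 genes passed in fish oil against control, and the smallest adjusted p was 0.9998. At an unadjusted p under 0.05 there were 349 genes, where chance alone gives 562, and no alternative called a gene at an adjusted p under 0.05. At an unadjusted p under 0.01 there were 81, where chance gives 112. Of the 45 lists, 6 passed with camera at the preset correlation, and 11, 10 and 11 did without control mouse 1, control mouse 5 or fish oil mouse 2. None passed with an estimated correlation or with fry. With camera on ranks 6 passed, but not the same 6: glycolysis and glycogen did not pass (adjusted p = 0.0712), and male-biased liver genes passed as lower (adjusted p = 0.0322).

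The list of PPAR-alpha targets passed with an adjusted p of 5.29e-09 (adjusted p = 0.269 with an estimated correlation). None of its 22 members passed alone, nor when adjusted over the list alone. Beside Cyp4a14, the members with the smallest p were Retsat, a retinol saturase, at 0.36 ± 0.11, Acot1, a cytosolic acyl-CoA thioesterase, at 0.95 ± 0.32, and Ehhadh, the bifunctional enzyme of peroxisomal oxidation, at 0.44 ± 0.18. The list of peroxisomal fatty acid oxidation had an adjusted p of 2.15e-05 (adjusted p = 0.269 with an estimated correlation). Its members Acot3 (0.59 ± 0.21) and Acot8 (0.36 ± 0.13), peroxisomal thioesterases, and Pex11a (0.48 ± 0.18), which takes part in peroxisome division, had positive values that did not pass, and no member passed adjusted over the list alone. Pdk4, which restrains pyruvate oxidation, was at 0.46 ± 0.34. Cpt1a, which admits fatty acids to mitochondria, was at 0.00 ± 0.26, with 1 of its 2 other probe sets opposite in sign. Ppara itself was at -0.28 ± 0.30. Without fish oil mouse 5, Cpt1a was at 0.25 and Ppara at 0.

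Genes of cholesterol synthesis were higher as a list (14 of 17 positive, median 0.20, adjusted p = 0.000776, and adjusted p = 0.567 with an estimated correlation). Lss, the lanosterol synthase, at 0.50 ± 0.15, was the 1 member higher when adjusted over the list alone. Hmgcs1 (0.46 ± 0.18) and Sqle (0.67 ± 0.37), enzymes of the early and middle pathway, and Hsd17b7 (0.35 ± 0.17), a later one, had positive values that did not pass. Srebf2, the regulator of that pathway, was at 0.25 ± 0.25. Without fish oil mouse 1 the list was no longer called (median 0.11, adjusted p = 0.0588).

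Fatty acid synthesis was lower as a list (adjusted p = 0.000267, and adjusted p = 0.567 with an estimated correlation), with Pklr lower when adjusted over the list alone. Elovl6, which elongates palmitate, was at -0.65 ± 0.28, and Acly, which supplies cytosolic acetyl-CoA, at -0.39 ± 0.20. Fasn (-0.30 ± 0.34), Srebf1 (-0.08 ± 0.28), its regulator, and Scd1 (-0.05 ± 0.14), a desaturase, did not pass. The list for glycolysis and glycogen was also lower (median -0.11, adjusted p = 0.0128, and adjusted p = 0.567 with an estimated correlation). Pklr was again its member called adjusted over the list alone, and the glycogen enzymes Pygl (-0.34 ± 0.14) and Ugp2 (-0.41 ± 0.17) were next. Both lists moved with fish oil mouse 5, the array with the low control ratios. Without it the adjusted p was 0.0801 for fatty acid synthesis (median -0.11) and 0.517 for glycolysis (median -0.05). Without it the log2 fold change was 0.01 for Fasn, 0.2 for Srebf1, -0.17 for Scd1, -0.23 for Acly and -0.22 for Pygl. Glycolysis was also not called without control mouse 3 (-0.07, adjusted p = 0.0539), with array weights (-0.06, adjusted p = 0.409) or with camera on ranks (adjusted p = 0.0712). Nor was it called with the pyruvate carboxylase (-0.07, 0.796) or beta-actin (-0.04, 0.127) ratio as a covariate. Fatty acid synthesis was not called with the pyruvate carboxylase covariate (-0.05, adjusted p = 0.129).

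Acute phase proteins, which the liver secretes in inflammation, were higher as a list (24 of 31 positive, median 0.21, adjusted p = 0.000776, and adjusted p = 0.729 with an estimated correlation). The metallothioneins Mt2 (1.24 ± 0.39) and Mt1 (0.67 ± 0.25), which bind metals, the NF-kappa-B inhibitor Nfkbia (0.47 ± 0.15) and the interleukin-1 antagonist Il1rn (0.60 ± 0.22) had the smallest p, and no member passed adjusted over the list alone. This list rested on fish oil mouse 3, without which its median was 0.03 and its adjusted p 0.484, while without fish oil mouse 5 its median was 0.38.

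Of the 18 fixed genes, none passed. The desaturases Fads1 and Fads2, which make long polyunsaturated fatty acids, were at -0.23 ± 0.31 and -0.42 ± 0.31, with the other Fads1 probe set opposite in sign. The bile acid enzymes Cyp7a1 and Cyp8b1 were at -0.10 ± 0.28 and -0.06 ± 0.19, and the sterol exporter Abcg5 at -0.09 ± 0.15. The gluconeogenic genes G6pc and Pck1 were at -0.32 ± 0.29 and 0.03 ± 0.29, and their coactivator Ppargc1a at -0.28 ± 0.21. These values moved with fish oil mouse 5: without it Fads1 was at 0.09, Fads2 at -0.07, Cyp8b1 at 0.14, Abcg5 at 0.05, G6pc at -0.09, Pck1 at 0.29 and Ppargc1a at -0.11. Of the 5 smallest p in each direction outside Pklr, Mgat2, an enzyme of N-glycan synthesis, was at -0.67 ± 0.16, and Blnk, a B cell adaptor, at -0.96 ± 0.25. The periportal gene Serpina12, a secreted protease inhibitor, was at -0.69 ± 0.18 and was lower when adjusted over the periportal list alone, a list that did not pass (adjusted p = 0.0508). Rnf11, a ubiquitin ligase, was at -0.36 ± 0.10, with 2 of its 3 other probe sets opposite in sign. Positive values were found for the noncoding RNAs Bvht (1.07 ± 0.27), Snhg3 (1.01 ± 0.26) and Hnf4aos (0.65 ± 0.17) and the actin regulator Eps8 (0.75 ± 0.19). The scaffold gene Grip2 had a mean log2 signal of 7.55 in fish oil and 5.89, under the filter, in control.

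**Figure D2:**
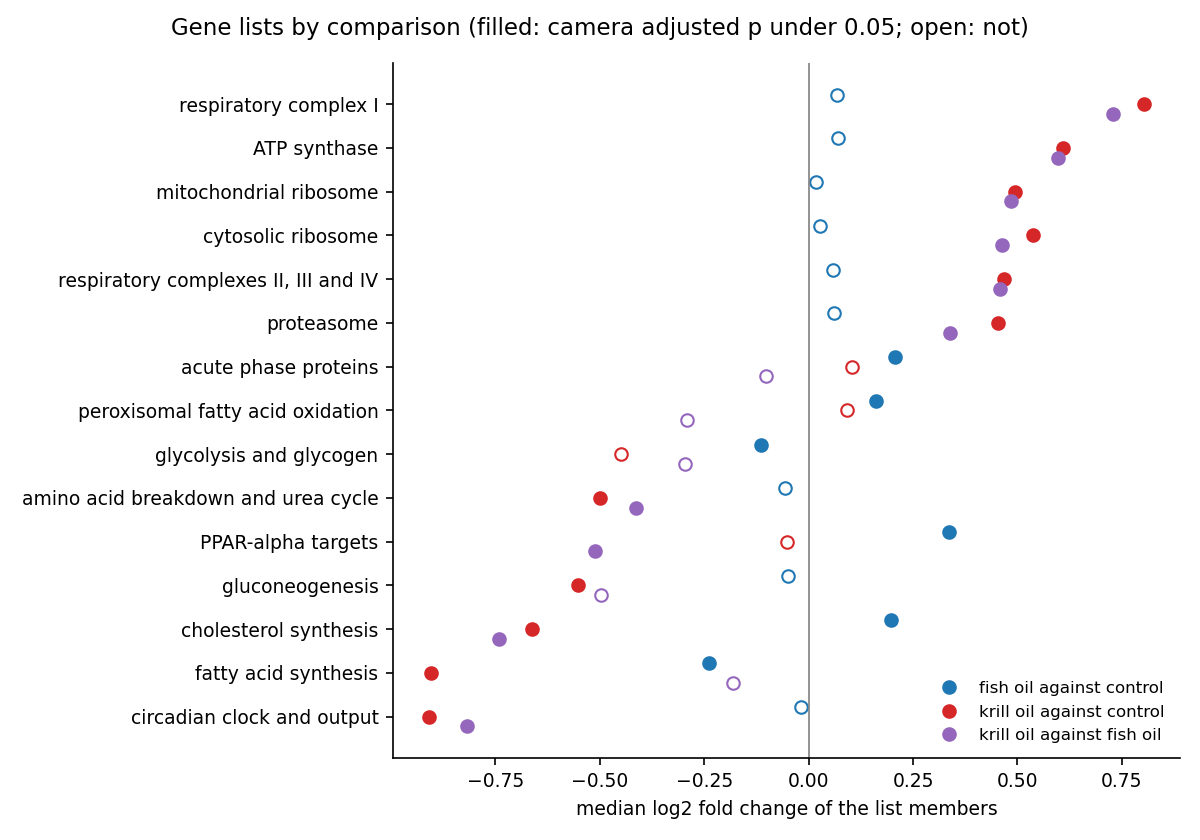
Median log2 fold change of the members of 15 gene lists in the 3 comparisons, with a filled point where camera's adjusted p passed at the preset correlation and an open point where it did not. Complex I has a median of 0.80 in krill oil against control and 0.73 in krill oil against fish oil, while PPAR-alpha targets are higher in fish oil against control (0.34).

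Krill oil was compared with the control diet to ask what krill oil did to gene expression in the liver. Genes of the ribosomes, the respiratory chain and the proteasome were higher: the mitochondrial ribosome (46 of 76 genes rose), respiratory complex I (25 of 34), the cytosolic ribosome (25 of 43) and the proteasome (22 of 38). Genes of lipid synthesis were lower, with 10 of 17 genes of cholesterol synthesis and 10 of 15 of fatty acid synthesis falling. The desaturases Fads1 and Fads2 fell by 2.03 ± 0.31 and 2.18 ± 0.31 on the log2 scale (SE, 7 mice per diet). Genes of amino acid breakdown (26 of 41), gluconeogenesis (11 of 19) and the circadian clock (12 of 19) fell too. All of these lists passed at camera's preset correlation and none with an estimated correlation (adjusted p from 0.636 to 0.702). The krill oil arrays also had lower pyruvate carboxylase and beta-actin ratios and brighter poly-A spikes than the control arrays. Fish oil mouse 5, with middle-to-3′ pyruvate carboxylase and beta-actin ratios as low, had the same sign of difference from its diet mates for 95.4% of the 1914 genes that changed by over 2-fold in krill oil.

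With limma, 5411 of 11245 genes passed (48.1%), 2297 higher and 3114 lower, and 581 of the higher and 1333 of the lower genes changed by over 2-fold. Centring each array on its median, in place of the deposited scaling, moved the median log2 difference of all genes from -0.026 to 0.261 and gave 4014 higher and 1884 lower genes, so the share of calls that were higher was 42.5% under one scaling and 68.1% under the other. The lists stayed called under median centring, but lower lists had smaller medians (-0.38 for cholesterol synthesis, -0.26 for gluconeogenesis, -0.21 for amino acid breakdown) and higher lists larger ones (0.78 for the mitochondrial ribosome, 0.74 for the proteasome). With the pyruvate carboxylase ratio as a covariate, a choice made after the data were seen, 153 genes were higher and 146 lower, and the 5 lists that were lower were not called: cholesterol synthesis (-0.09, adjusted p = 0.984), fatty acid synthesis (-0.35, 0.916), gluconeogenesis (-0.05, 0.916), amino acid breakdown (0.04, 0.495) and the clock (-0.54, 0.126). The 6 higher lists were called, with smaller medians for complex I (0.51) and the cytosolic ribosome (0.22). With the beta-actin ratio 4 of the 5 lower lists, all but the clock, were not called (medians from -0.52 to -0.33, adjusted p from 0.0678 to 0.175).

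Among the largest falls were those of Reep6, a protein of the endoplasmic reticulum (-4.61 ± 0.47, adjusted p = 4.36e-07), Sema4g, a semaphorin (-4.08 ± 0.50), and Hnrnpab, an RNA-binding protein (-4.04 ± 0.31). Other genes fell to a krill oil mean under 6.43, the level of the filter, where signal was not set apart from background here, so the sizes and the order of their falls are not known. Mean log2 signals in control and krill oil were 10.11 and 4.57 for Nfic, a transcription factor (adjusted p = 2.29e-07), and 9.40 and 4.52 for Nxf1, the exporter of messenger RNA (adjusted p = 1.27e-06). They were 8.75 and 4.27 for Spg7, a mitochondrial protease, and 8.26 and 4.12 for Txndc11, a thioredoxin-domain protein. Atp6v0a1, a proton pump subunit, was at 8.52 and 4.57, but its other probe set was opposite in sign, and its log2 fold change was 1.10 (adjusted p = 0.0956) under quantile scaling. Among the largest rises were those of Mtm1, a lipid phosphatase (2.67 ± 0.49, adjusted p = 0.000113), Themis, known from T cell development (2.49 ± 0.39), and 4930459C07Rik (2.34 ± 0.44). So were those of Pfdn4, a prefoldin chaperone subunit (2.23 ± 0.26), Pet100, which assembles cytochrome oxidase (2.21 ± 0.23), the acute phase protein Saa1 (2.21 ± 0.58) and Gm3715 (2.17 ± 0.60). Zfp982, a zinc finger gene, rose from a control mean of 5.88, under the filter, to 8.48 (adjusted p = 0.0142). In fish oil mouse 5, Nxf1 was at 4.70 on the log2 scale, beside 9.55 ± 0.20 (SD, n = 6) in the other fish oil mice and 4.52 in krill oil.

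The mitochondrial lists had medians of 0.49 for the mitochondrial ribosome (46 higher and 13 lower of 76, adjusted p = 2.66e-06), 0.80 for complex I (25 and 6 of 34, 5.96e-06), 0.47 for complexes II to IV (14 and 3 of 25, 0.0054) and 0.61 for ATP synthase (10 and 2 of 16, 0.00595). For each of these 4 lists, adjusted p = 0.636 with an estimated correlation. Adjusted over the list alone, 50 and 13, 26 and 6, 14 and 3, and 10 and 2 members passed. Ndufb2 and Ndufs5, accessory subunits of complex I, rose by 1.57 ± 0.20 and 0.86 ± 0.12. Uqcr11 of complex III rose by 1.15 ± 0.16, Cox4i1 of complex IV by 0.98 ± 0.14, Atp5l of ATP synthase by 1.47 ± 0.20, and the ribosomal genes Mrpl14 and Mrpl55 by 1.83 ± 0.19 and 1.66 ± 0.17. Sdha, the catalytic subunit of complex II, fell by 1.45 ± 0.23. These lists were also higher in fish oil mouse 5 than in the other 6 fish oil mice, by a median of 0.58 for complex I, 0.46 for complexes II to IV, 0.57 for ATP synthase and 0.23 for the mitochondrial ribosome. Under quantile scaling, complexes II to IV (0.17, adjusted p = 0.265) and ATP synthase (0.39, adjusted p = 0.277) were no longer called. Not all mitochondrial genes rose. The list of the tricarboxylic acid cycle and pyruvate dehydrogenase had 4 higher and 9 lower of 22 and did not pass with camera (median -0.20, adjusted p = 0.337).

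The cytosolic ribosome had a median of 0.54 (25 higher and 4 lower of 43, adjusted p = 1.13e-05) and the proteasome one of 0.45 (22 and 4 of 38, 0.000769). For both, adjusted p = 0.636 with an estimated correlation, and adjusted over the list alone 25 and 4, and 22 and 5, members passed. Rpl11 rose by 1.06 ± 0.16, and Rps4x, another ribosomal protein gene, fell by 1.13 ± 0.15. The core proteasome subunits Psma7 and Psma2 rose by 1.74 ± 0.22 and 1.31 ± 0.18. In fish oil mouse 5 the list medians were 0.72 and 0.21 above the other fish oil mice.

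Cholesterol synthesis had a median of -0.66 (0 higher and 10 lower of 17, adjusted p = 0.0105, and adjusted p = 0.636 with an estimated correlation). Fatty acid synthesis had one of -0.90 (1 higher and 10 lower of 15, adjusted p = 0.0307, and adjusted p = 0.702 with an estimated correlation). Adjusted over the list alone, the counts were 10 lower, and 1 higher and 10 lower. Dhcr7, the last enzyme of the cholesterol pathway, fell by 1.44 ± 0.22, Pmvk, of the mevalonate steps, by 1.0 ± 0.19, and Sqle, which makes squalene epoxide, by 1.44 ± 0.37. The regulators Srebf2 and Srebf1 fell by 1.13 ± 0.25 and 1.2 ± 0.28. Mlxipl, the carbohydrate-sensing factor ChREBP, fell by 2.46 ± 0.29, Fasn by 1.66 ± 0.34, and Acaca, which makes malonyl-CoA, by 1.39 ± 0.23. Elovl6 was at -0.46 ± 0.28 (adjusted p = 0.187), and passed with the mean of its probe sets (-0.86, adjusted p = 0.0113). Scd1 was at 0.29 ± 0.14 (adjusted p = 0.0976), with its other probe set opposite in sign, and its value depended on the processing: the mean of its probe sets gave -1.0 (adjusted p = 7.2e-05), and median centring gave 0.58 (adjusted p = 0.00254). Fads1 and Fads2 had adjusted p of 1.97e-05 and 8.05e-06, and their list of polyunsaturated fatty acid synthesis, with 2 higher and 4 lower of 6 genes, did not pass (adjusted p = 0.384), but passed as lower under quantile scaling (-0.89, adjusted p = 0.0212). In fish oil mouse 5 the medians of the cholesterol and fatty acid synthesis lists were -0.48 and -1.11 against the other fish oil mice, and its Fads1 signal was 11.65, beside 13.88 ± 0.17 (SD, n = 6). Without control mouse 7 or krill oil mouse 7, fatty acid synthesis was not called, with medians about as large (-0.85, adjusted p = 0.0525, and -0.88, adjusted p = 0.0652).

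**Figure D3:**
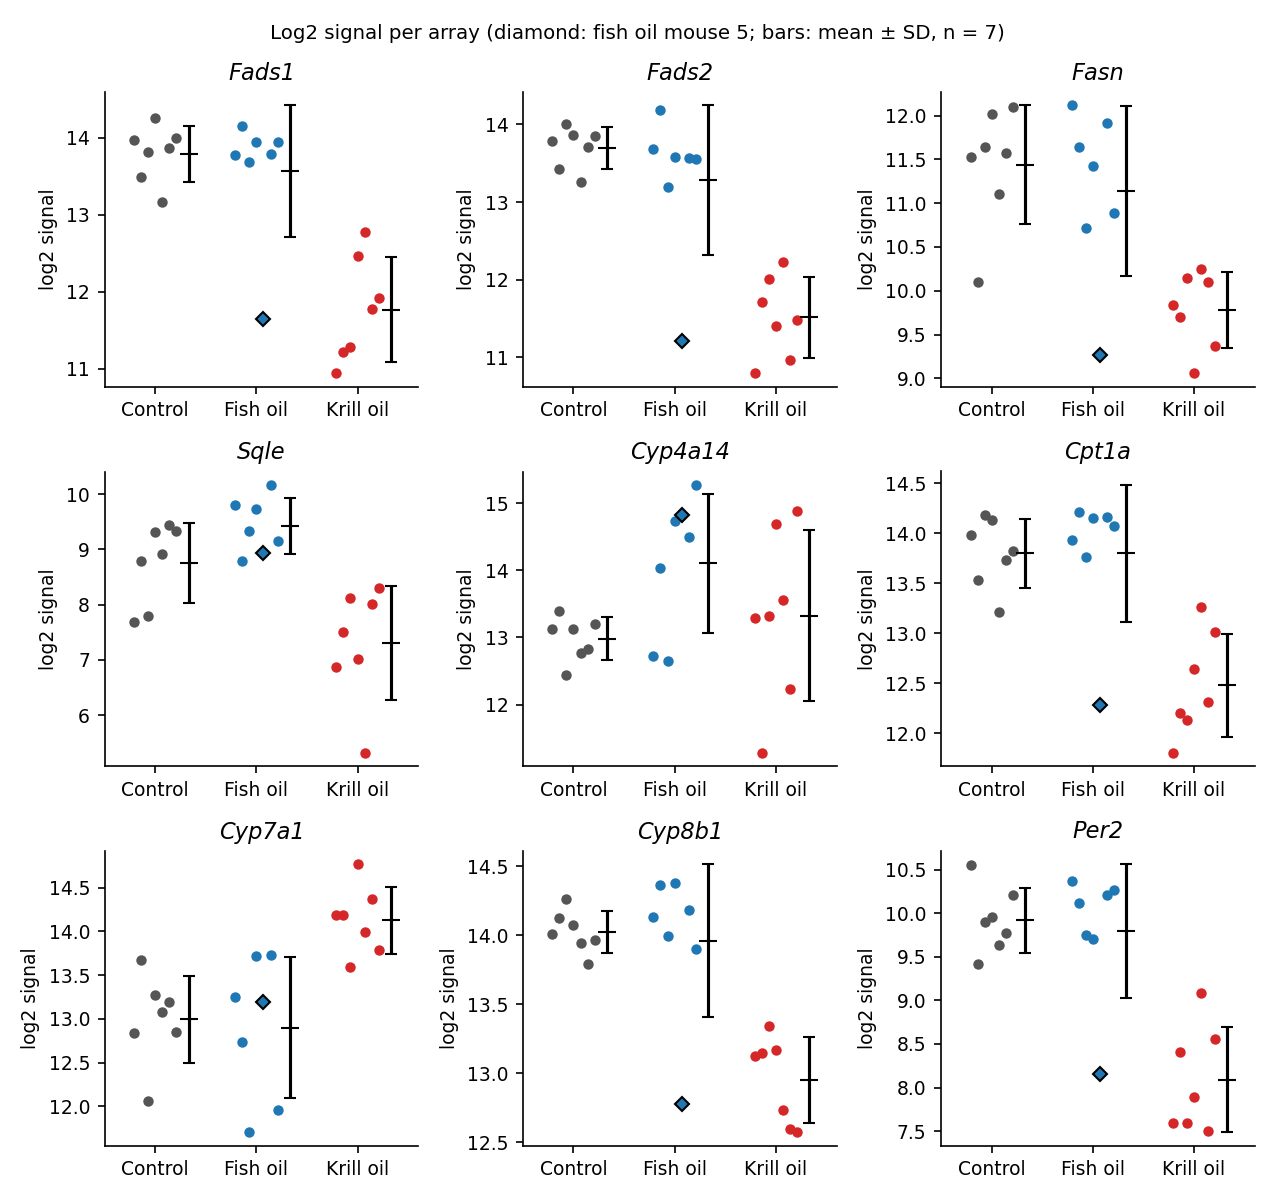
Log2 signal of 9 genes of lipid metabolism, bile acid synthesis and the clock in each of the 21 arrays, with the mean ± SD of each diet. Fish oil mouse 5 (diamond) lies with the krill oil mice for Fads1 (11.65), Fads2 and Cyp8b1 and with its own diet for Cyp7a1 (13.20).

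Gluconeogenesis had a median of -0.55 (1 higher and 11 lower of 19, adjusted p = 0.0442, and adjusted p = 0.636 with an estimated correlation), with 1 higher and 13 lower when adjusted over the list alone. Pck1, the pathway's committed enzyme, fell by 1.40 ± 0.29, Mdh2, a malate dehydrogenase, by 1.63 ± 0.24, and Gcgr, the glucagon receptor, by 1.05 ± 0.15. G6pc, which releases free glucose, fell by 0.71 ± 0.29 (adjusted p = 0.0465), and Ppargc1a by 0.59 ± 0.21 (adjusted p = 0.0257), and neither passed under median centring (-0.42, adjusted p = 0.245, and -0.3, adjusted p = 0.24). Amino acid breakdown and the urea cycle had a median of -0.50 (4 higher and 26 lower of 41, adjusted p = 0.00379, and adjusted p = 0.636 with an estimated correlation), the same counts as adjusted over the list alone. Ivd, of leucine breakdown, fell by 1.19 ± 0.13 and Fah, of tyrosine breakdown, by 1.49 ± 0.19. In fish oil mouse 5 both lists were lower than in its diet mates, by medians of -1.05 and -0.83. Gluconeogenesis was not called in 5 of the fits without a single mouse: control 3 (median -0.46, adjusted p = 0.0637), control 5 (-0.55, 0.0788), control 7 (-0.63, 0.0518), krill oil 6 (-0.54, 0.0669) and krill oil 7 (-0.55, 0.0658). It was also not called with a stricter filter (-0.52, 0.103) or with the replicate number as a block (-0.55, 0.0567), so its size held while its p passed to the other side of the threshold.

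The circadian clock and its output had a median of -0.91 (0 higher and 12 lower of 19, adjusted p = 0.00439, and adjusted p = 0.636 with an estimated correlation), with 12 lower adjusted over the list alone. The clock repressors Per2, Per3 and Bhlhe40 fell by 1.83 ± 0.29, 1.54 ± 0.30 and 1.70 ± 0.28. In fish oil mouse 5 the list's median was -0.57 against its diet mates, and Per2 was at 8.15, beside 10.07 ± 0.28 (SD, n = 6). The time of day at which livers were taken is not in the labels.

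Fatty acid oxidation moved in parts. Ppara fell by 2.53 ± 0.30 (adjusted p = 2.36e-06), and Cpt1a fell by 1.32 ± 0.26. Cyp4a12a, a male-biased omega-hydroxylase, fell by 3.87 ± 0.44. In the mitochondrial oxidation list, 6 genes were higher and 12 lower of 22, and the list did not pass (median -0.36, adjusted p = 0.214), but passed as lower under quantile scaling (-0.57, adjusted p = 0.00135) and without the filter (-0.36, adjusted p = 0.0265). Acadl and Hadha, enzymes of beta-oxidation, fell by 0.68 ± 0.11 and 0.86 ± 0.16. PPAR-alpha targets, with 2 higher and 4 lower of 22, did not pass (adjusted p = 0.733), and Cyp4a14 (0.34 ± 0.45) and Pdk4 (0.45 ± 0.34) did not either. Bile acid genes went both ways, with 6 higher and 10 lower of 21, and the list (median -0.23, adjusted p = 0.513) passed as lower under quantile scaling (-0.59, adjusted p = 0.0227). Cyp7a1, the rate-limiting enzyme, rose by 1.13 ± 0.28 (adjusted p = 0.00193). Cyp8b1, which sets the share of cholic acid, and Cyp27a1, of the acidic pathway, fell by 1.07 ± 0.19 and 1.04 ± 0.17, and Abcg5 fell by 0.52 ± 0.15, but did not pass under median centring (-0.23, adjusted p = 0.238). Cyp7a1 in fish oil mouse 5 was at 13.20, beside 12.85 ± 0.87 (SD, n = 6) in its diet mates and 14.13 in krill oil, whereas Ppara was at 11.69, beside 13.64 and 11.12.

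Markers of other cells and interferon genes were examined beside these groups, and none of their lists passed in the chosen analysis. Of 20 Kupffer cell markers, 7 were higher and 2 lower (adjusted p = 0.133). The oxidase subunit Cybb and the scavenger protein Cd5l rose by 0.84 ± 0.19 and 0.93 ± 0.22, and the Fc receptor chain Fcer1g fell by 0.88 ± 0.24. Of 6 erythroid markers, 2 were higher (adjusted p = 0.172): the globin gene Hbb-b2 by 0.91 ± 0.23 and Alas2, of heme synthesis, by 0.55 ± 0.14. With the mean of a gene's probe sets, Cybb (0.4, adjusted p = 0.0665) and Hbb-b2 (0.49, adjusted p = 0.0731) did not pass. Of 21 stellate cell markers, 6 were higher (adjusted p = 0.18). Of 31 interferon response genes, 4 were higher and 13 lower (adjusted p = 0.13), among them the transcription factors Irf7 and Stat2, which fell by 1.0 ± 0.18 and 1.61 ± 0.30. The interferon list passed as lower without the filter (median -0.41, adjusted p = 0.00273) and with the pyruvate carboxylase (-0.71, 0.000539) or beta-actin (-0.53, 0.00605) covariate. The Kupffer cell list passed as higher with either covariate (0.31, adjusted p = 0.0301, and 0.24, 0.019). Alas2 and Irf7 in fish oil mouse 5 were at 11.39 and 10.34, beside 11.67 and 10.15 in its diet mates and 12.32 and 9.42 in krill oil. The other genes named here differed from its diet mates in the krill oil direction. Stat2 was at 7.44, beside 8.95 in its diet mates and 7.51 in krill oil. The same values were 9.5, 8.69 and 9.64 for Cybb, and 11.47, 11.05 and 11.9 for Cd5l. They were 8.95, 8.45 and 9.62 for Hbb-b2, and 8.3, 8.51 and 7.26 for Fcer1g. Against its diet mates, the list medians in this mouse were 0.27 for Kupffer cell markers and 0.53 for the interferon response.

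**Figure D4:**
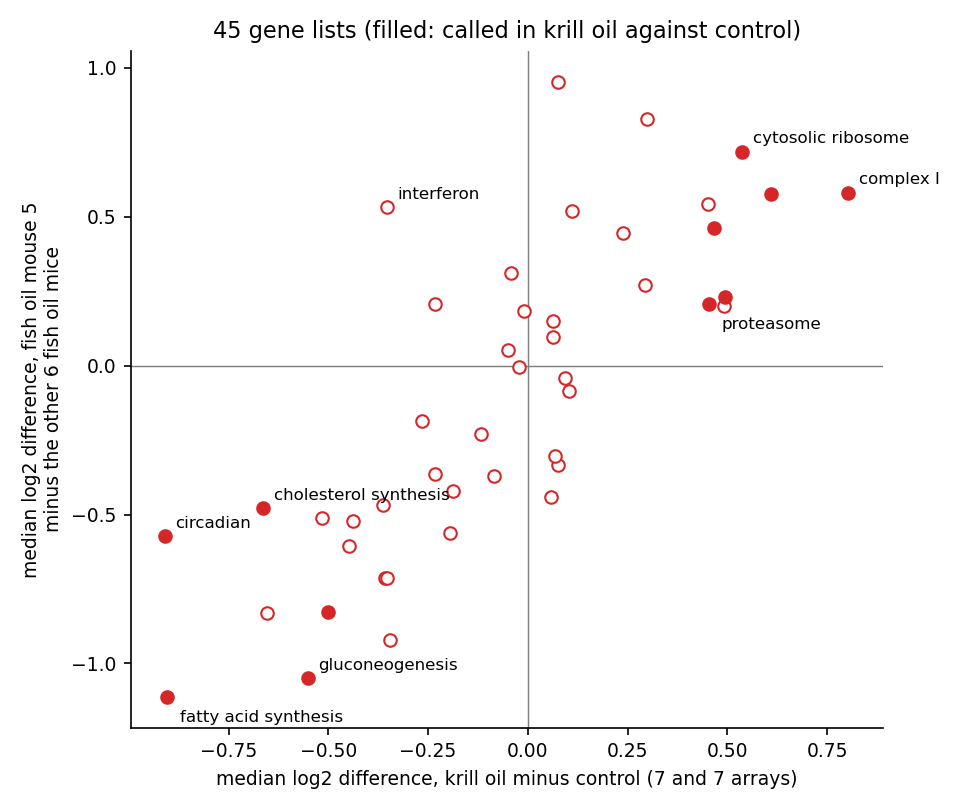
Median log2 difference of 45 gene lists in krill oil minus control (x axis) and in fish oil mouse 5 minus the other 6 fish oil mice (y axis), with filled points for the lists called in krill oil against control. The correlation across lists is 0.786, and the interferon response list lies at -0.35 on the x axis and 0.53 on the y axis.

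Krill oil was compared with fish oil to ask the series' own question, whether the sources differ at a similar omega-3 content. The krill oil livers had lower expression of cholesterol synthesis genes (12 of 17 fell) and of PPAR-alpha targets (10 of 22 fell, 0 rose) than the fish oil livers. They had higher expression of mitochondrial ribosome, respiratory chain, cytosolic ribosome and proteasome genes, and lower expression of clock and amino acid breakdown genes. None of these lists passed with an estimated correlation (adjusted p = 0.755). Lss, the lanosterol synthase, was lower by a log2 difference of -1.04 ± 0.15 (SE, 7 mice per diet), and Sqle by one of -2.11 ± 0.37. The krill oil arrays also had a lower pyruvate carboxylase ratio than the fish oil arrays, and their beta-actin ratio passed as lower without fish oil mouse 5 (adjusted exact permutation p = 0.00752) but not with it (0.0548).

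With limma, 5112 genes passed (45.5%), 2136 higher and 2976 lower, and 456 and 1230 of them differed by over 2-fold. Centring on the median moved the median log2 difference from -0.046 to 0.222, with 3593 higher and 1849 lower genes, so the share that was higher went from 41.8% to 66%. The lists stayed called, with medians of -0.47 for cholesterol synthesis, -0.24 for PPAR-alpha targets, -0.14 for amino acid breakdown and 0.61 for the proteasome. With the pyruvate carboxylase ratio as a covariate, 531 genes were higher and 695 lower, and the 4 lists that were lower were not called: cholesterol synthesis (-0.44, adjusted p = 0.0898), PPAR-alpha targets (-0.54, 0.0506), amino acid breakdown (-0.09, 0.89) and the clock (-0.55, 0.0828). The 6 higher lists were called, with smaller medians for ATP synthase (0.38) and the cytosolic ribosome (0.25).

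Among the largest rises over fish oil were those of Mtm1 (2.43 ± 0.49), osteomodulin, Omd (2.19 ± 0.26), the flap endonuclease Fen1 (2.12 ± 0.50) and Pet100 (1.98 ± 0.23). Zfp982, 4930459C07Rik and the neutrophil gene S100a8 rose from fish oil means under the filter's 6.43 (5.18, 6.32 and 5.47) to 8.48, 9.1 and 7.5, so the sizes and the order of these rises are not known. Gm3715 (2.35 ± 0.60) was at 10.57 in fish oil mouse 5 and between 5.17 and 6.48 in its diet mates. Their mean of 5.9 lay under the filter, so the size of this rise is not known either. Fish oil mouse 5 was at or above the krill oil mean in Mtm1 (13.13, beside 12.1 in krill oil and 9.09 in its diet mates) and Fen1 (10.66, 10.52 and 8.03). So it was in Zfp982 (9.95, 8.48 and 4.38) and S100a8 (7.51, 7.5 and 5.13). It was below that mean in Omd (10.92, 11.5 and 9.04), Pet100 (12.49, 13.17 and 10.98) and 4930459C07Rik (7.09, 9.1 and 6.19). The adjusted p of these 8 genes ran from 3e-06 (Omd) to 0.00529 (S100a8). Among the largest falls were those of Reep6 (-4.47 ± 0.47), Sema4g (-3.94 ± 0.50) and Nfix, a relative of Nfic (-3.77 ± 0.53). In 5 genes the krill oil mean lay under the filter and the size of the fall is again not known. Mean log2 signals in fish oil and krill oil were 10.3 and 4.57 for Nfic, 8.86 and 4.52 for Nxf1, 8.36 and 4.27 for Spg7, 8.18 and 4.35 for Pacs2, a sorting protein, and 7.91 and 4.12 for Txndc11. The adjusted p of the 8 falls ran from 1.76e-07 (Nfic) to 0.000123 (Txndc11).

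Cholesterol synthesis had a median of -0.74 (0 higher and 12 lower of 17, adjusted p = 0.000235, and adjusted p = 0.755 with an estimated correlation), with 14 lower adjusted over the list alone. Dhcr7 was at -1.37 ± 0.22, Srebf2 at -1.39 ± 0.25 and Srebf1 at -1.11 ± 0.28, and all passed. PPAR-alpha targets had a median of -0.51 (adjusted p = 0.0309, and adjusted p = 0.755 with an estimated correlation), with 10 lower adjusted over the list alone. Cyp4a12a (-3.60 ± 0.44), Cpt1a (-1.32 ± 0.26) and Acadm, of medium-chain oxidation (-0.75 ± 0.17), fell. Gpd1, of glycerol phosphate synthesis, was at -0.88 ± 0.15, with 1 of its 2 other probe sets opposite in sign and a mean of its probe sets of -0.34 (adjusted p = 0.0561). Cyp4a14 was at -0.78 ± 0.45 (adjusted p = 0.16) and Pdk4 at -0.02 ± 0.34. The PPAR-alpha list was not called without fish oil mouse 5 (median -0.52, adjusted p = 0.0512), fish oil mouse 7 (-0.43, 0.0608), krill oil mouse 1 (-0.41, 0.0574) or krill oil mouse 2 (-0.46, 0.092), nor with the mean of probe sets (-0.47, adjusted p = 0.0537).

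The lists that were higher were the mitochondrial ribosome (46 higher and 10 lower of 76, median 0.49, adjusted p = 2.22e-06), complex I (25 and 5 of 34, 0.73, 9.16e-06), the cytosolic ribosome (24 and 4 of 43, 0.46, 3.17e-05) and the proteasome (19 and 5 of 38, 0.34, 0.00167). ATP synthase (9 and 1 of 16, 0.60, 0.00586) and complexes II to IV (14 and 4 of 25, 0.46, 0.00863) followed. For all 6 lists, adjusted p = 0.755 with an estimated correlation. Mrps28 and Mrpl14 rose by 1.54 ± 0.19 and 1.53 ± 0.19, Ndufb2 by 1.51 ± 0.20, Uqcr11 by 1.05 ± 0.16, Atp5l by 1.25 ± 0.20, Psma7 by 1.51 ± 0.22 and Rpl11 by 0.95 ± 0.16, while Rps4x fell by 1.05 ± 0.15. Under quantile scaling, ATP synthase (0.33, adjusted p = 0.316) and complexes II to IV (0.10, adjusted p = 0.351) were not called.

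The clock list (0 higher and 11 lower of 19, median -0.82, adjusted p = 0.00767) and the list of amino acid breakdown and urea cycle (4 and 24 of 41, -0.41, 0.0094) were lower. For both, adjusted p = 0.755 with an estimated correlation. Bhlhe40 fell by 1.89 ± 0.28, Per2 by 1.70 ± 0.29 and the repressor Cry2 by 1.2 ± 0.23. Ivd fell by 1.31 ± 0.13 and Fah by 1.28 ± 0.19. Amino acid breakdown was not called with the beta-actin covariate (-0.35, adjusted p = 0.083). Among the erythroid markers, Alas2 rose by 0.69 ± 0.14 and Hbb-b2 by 1.09 ± 0.23, though their list did not pass (adjusted p = 0.16).

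Of the 18 fixed genes, Ppara fell by 2.25 ± 0.30, Fads1 and Fads2 by 1.80 ± 0.31 and 1.77 ± 0.31, Fasn by 1.36 ± 0.34, Pck1 by 1.43 ± 0.29, Cyp8b1 by 1.01 ± 0.19 and Abcg5 by 0.43 ± 0.15 (-0.16, adjusted p = 0.418, under median centring). Cyp7a1 rose by 1.23 ± 0.28 (adjusted p = 0.00101). Scd1 (0.34 ± 0.14, adjusted p = 0.0573), Elovl6 (0.19 ± 0.28), G6pc (-0.39 ± 0.29) and Ppargc1a (-0.31 ± 0.21) did not pass, and the other Scd1 probe set, 1 of 2 for Elovl6 and 1 of 4 for Ppargc1a were opposite in sign. The mean of the Scd1 probe sets gave -0.77 (adjusted p = 0.00107), while Scd1 passed as higher with median centring (0.6, adjusted p = 0.00185), a stricter filter (0.34, adjusted p = 0.0416) and array weights (0.41, adjusted p = 0.00371). Without fish oil mouse 5, Scd1 (0.45, adjusted p = 0.00192), G6pc (-0.62, adjusted p = 0.0418) and Ppargc1a (-0.49, adjusted p = 0.0286) passed.

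The fish oil and krill oil effects against control were compared across genes to ask whether the oils moved the liver in one direction. The correlation across 11245 genes was 0.329, where unchanged groups that share the same controls gave 0.5 on average in 100 simulated draws. With controls 1 to 3 for fish oil and 4 to 7 for krill oil it was 0.36, and the other way round 0.04, where unchanged groups gave 0.001 and 0.002. Without fish oil mouse 5 it was -0.10, where unchanged groups gave 0.483, and with split controls 0.017 and -0.312, where they gave 0 and 0.001, so its sign rested on that array. The covariance was 0.0609 with all arrays, beside 0.034 for unchanged groups, and -0.0188 without fish oil mouse 5, beside 0.0342. Genes are not independent replicates, and no overlap of called genes could be counted, since fish oil had none.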

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

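Of the tests of explanations below, those on the krill oil pattern, on fish oil mouse 5 and on PPAR-alpha targets without that mouse or with a covariate were chosen after the result was seen, while the counts over other splits of the samples were planned.

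The krill oil pattern runs with the control ratios of the arrays. Both middle-to-3′ ratios of pyruvate carboxylase separate krill oil from control without overlap, so diet and RNA quality cannot be told apart by the groups alone. The 5′-to-3′ ratio of pyruvate carboxylase overlaps, with krill oil mouse 2 at 0.099 and control mouse 1 at 0.0938. Fish oil mouse 5, not fed krill oil by its label, carries the pattern: its difference from its diet mates correlates with krill oil against control at 0.711 across 11245 genes. The other 13 arrays of mice not fed krill oil range from -0.451 to 0.573, with control 5 at 0.573 and control 2 at 0.316. The test cannot decide whether diet alone is the explanation, since a wrong label stays open for fish oil mouse 5. The bound of this test was set after these values were known. RNA integrity may account for part of the lists that are higher, since the 6 respiratory chain, ribosome and proteasome lists have a median difference of 0.518 in fish oil mouse 5 as well. With the middle-to-3′ pyruvate carboxylase ratio as a covariate all 6 stayed called at the preset correlation, with a median over the lists of 0.475. Complex I went from 0.80 to 0.51 and the cytosolic ribosome from 0.54 to 0.22. Since this ratio separates krill oil from control, the fit takes its slope from differences within diets. It cannot decide whether a linear trend on the ratio is the whole cause of the rise of these lists. Within diets, however, the pyruvate carboxylase ratio and the position on the pattern gave r = -0.208 over 13 arrays (permutation p = 0.606, adjusted 0.606 over 2 relations). Spearman's rho was 0.033 (permutation p = 0.947), and r was 0.30 without the 2 arrays farthest from the median (permutation p = 0.404). The beta-actin ratio gave r = -0.334 (permutation p = 0.409, adjusted 0.606). Fish oil mouse 5 was left out of these relations. It had a pyruvate carboxylase ratio of 0.025 and lay at 0.904 on the pattern, where the 13 arrays ran from -0.214 to 0.332. These relations decide nothing.

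Fish oil mouse 5 is the array that stands apart most often. An exchange of its label with that of a krill oil mouse is argued against by the middle-to-3′ ratio of pyruvate carboxylase. The highest krill oil value was 0.0538, and the other 6 fish oil arrays started at 0.1398. On the 5′-to-3′ ratio, krill oil mouse 2 (0.099) lay within the range of those 6 arrays (0.0906 to 0.127). A single wrong label of fish oil mouse 5 stays open. A difference in RNA input or integrity is a candidate explanation: its poly-A spike signal, added to the total RNA, was 13327.9, which is 3.15 times the next highest array. Its hybridisation spikes were the brightest too (20217.1, beside 12063.9 for the next), and the log2 difference between the spikes was -0.601, beside -1.281 for the next array. No biological explanation was tested for this mouse.

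PPAR-alpha targets were higher in fish oil, and the low ratios of fish oil mouse 5 do not account for it, since the list's median was 0.333 without that array. In 2 of 100 splits of the 14 arrays the list had a camera p as small, the real one included (1.18e-10, and 2.1e-13 for the smallest p of the others). The list had the smallest camera p of the 45 lists in these same data, so the count of splits cannot exclude chance. With the middle-to-3′ pyruvate carboxylase ratio as a covariate, the list stayed called at camera's preset correlation with a median of 0.34 (adjusted p = 9.39e-08). Fatty acid synthesis and glycolysis lost their calls in that fit. The fit takes its slope from differences within diets. Fish oil mouse 5 had a ratio of 0.025, beside 0.1398 to 0.1867 in its diet mates, from which the list differed there by a median of 0.054. A slope that leans on that array could hardly change the list, so the fit cannot decide whether a linear trend on the ratio is the cause. Without mouse 5, 1 of 5 control ratios was lower in fish oil than in control, the second middle-to-3′ ratio of pyruvate carboxylase (0.323 against 0.429, exact permutation p = 0.0175, adjusted 0.0394), and the other 4 did not pass (adjusted exact permutation p from 0.056 to 0.935). The diet stays a hypothesis, found and tested on the same data.

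For the counts of genes, 1 of 100 splits of the krill oil and control arrays gave as many as the real 5411, itself included, with 4285 in the highest other. For krill oil against fish oil, 1 of 100 gave as many as 5112, with 2953 in the highest other. Chance is argued against for both, as far as 100 splits can show, and the median of the other splits was 0 genes in each. These counts do not separate diet from the RNA quality that differs between the same groups. For fish oil against control, all 100 of 100 splits gave as many as the real 0, with 1 in the highest other. No split can give fewer than 0, so that result was fixed beforehand and decides nothing. For the counts of lists chance cannot be excluded: 12 of 100 splits gave as many as the 11 of krill oil against control (highest other 17), 42 as many as the 10 of krill oil against fish oil (20), and 79 as many as the 6 of fish oil against control (20).

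A sample was singled out when its gap to the nearest other array of its diet was large for the range of the 7. Of 402 sets of 7 values, 73 held such a sample, where chance gives about 1 in 20, or 20.1, and 61 of the 73 were fish oil mouse 5.

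Among the array measures, fish oil mouse 5 was lowest of its diet in the pyruvate carboxylase ratio (0.025), the beta-actin ratio (0.285), the glyceraldehyde-3-phosphate dehydrogenase ratio (0.981) and the median correlation with control arrays (0.814). It was highest in mean log2 signal of the poly-A spikes (13.7) and in the scores on the first (69.6) and second (65.3) principal components. Fish oil mouse 2 had the highest 75th percentile of signal (400.8).

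Among the mean log2 signals of lists, fish oil mouse 5 was lowest for glycolysis and glycogen (9.94), amino acid breakdown and urea cycle (12.36), the circadian clock (9.41) and gluconeogenesis (11.31). It was highest for complex I (13.74), the cytosolic ribosome (13.84) and ATP synthase (14.46). Fish oil mouse 3 was highest for acute phase proteins (14.07) and for the gene Saa1 (16.07), and lowest for 4930459C07Rik (3.78).

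The log2 signals of these genes of lipid and bile acid metabolism were lowest of the diet in fish oil mouse 5: Cpt1a (12.28), Cyp8b1 (12.78), Cyp27a1 (12.51), Ppara (11.69), Srebf1 (10.22), Abcg5 (11.18), Fads1 (11.65), Fads2 (11.21), Mlxipl (10.6), Cyp4a12a (10.61), Hadha (11.97), Acadm (13.87) and Rxra (10.13). So were those of glucose, amino acid and energy metabolism, namely Pygl (12.57), Ppargc1a (7.97), Gcgr (11.25), Mdh2 (11.24), Ivd (10.98), Fah (13.15) and Sdha (12.12), and the detoxifying enzymes Cyp1a2 (11.31) and Gstm1 (10.98). The clock genes Per2 (8.15), Bhlhe40 (9.48) and Cry2 (8.47) were lowest there as well, as were Stat2 (7.44), Rps4x (13.75), Nfic (7.98), Nfix (8.47), Nxf1 (4.7), Reep6 (11.05), Spg7 (3.63), Txndc11 (3.35) and Sema4g (9.54).

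The log2 signals highest of the diet in fish oil mouse 5 were those of Mtm1 (13.13), Pfdn4 (11.5), Pet100 (12.49), Gm3715 (10.57), Omd (10.92), Ndufb2 (14.5), Uqcr11 (15.1), Cox4i1 (15.7), Atp5l (15.18), Mrpl14 (12.63), Rpl11 (14.99), Psma7 (13.71) and Gpx4 (15).

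Elsewhere, krill oil mouse 5 was lowest for Hnf4aos (8.37) and highest for Spg7 (7.33), krill oil mouse 6 was highest for Themis (10.02), and fish oil mouse 6 was lowest for S100a8 (1.8). Control mouse 5 was lowest for Reep6 (12.75) and Txndc11 (5.17), control mouse 2 lowest for Acaca (9.11), and control mouse 1 highest for Gcgr (12.15).

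Probe sets that name no gene were outside the comparisons. Tested by themselves with limma, 1333 of them passed in krill oil against control and 1176 in krill oil against fish oil, and 0 in fish oil against control.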

How the results depend on the processing

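The covariate fits, the fits without fish oil mouse 5 or with 2 mice left out, and the counts of lists without single mice were chosen after seeing the data. Fish oil against control had 0 genes past the threshold at an adjusted p under 0.05 in every alternative run, and 47 higher and 34 lower at an unadjusted p under 0.01. The krill oil comparisons stayed within 1.5 times their counts of genes under the other filters, scalings and models run, apart from those named next. Leaving out each mouse in turn gave 2087 to 2495 higher and 2815 to 3294 lower genes for krill oil against control, 1908 to 2576 and 2708 to 3423 for krill oil against fish oil, and 0 to 0 in both directions for fish oil against control. Lists called ranged from 5 to 11 for fish oil (11 without control 1, 10 without control 5, 11 without fish oil 2), 9 to 12 for krill oil against control and 9 to 11 for krill oil against fish oil.

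Median centring gave 4014 higher and 1884 lower genes for krill oil against control and 3593 and 1849 for krill oil against fish oil, from the shift of all values that it makes. All krill oil lists stayed called under it, but the median of amino acid breakdown against fish oil went from -0.41 to -0.14. Every probe set by itself, 22519 features in place of 11245, gave 3868 and 6604, and 3580 and 6051. The share of calls that were higher went from 42.5% to 36.9% against control and from 41.8% to 37.2% against fish oil. The cause of that shift was not tested. The pyruvate carboxylase covariate gave 153 and 146, and 531 and 695, and 12 lists for fish oil. Of the 299 genes it called for krill oil against control, 209 were also called in the same direction without it and 2 in the opposite direction, and of the 1226 for krill oil against fish oil 986 were. The covariate and the krill oil diet overlap, so the loss of calls cannot be assigned to either. The beta-actin covariate gave 1264 and 1786 for krill oil against control. Lists called were 17 and 16 in the krill oil comparisons under quantile scaling, where those added against control were all lower and included bile acids, mitochondrial fatty acid oxidation and glycolysis (-0.44, adjusted p = 0.00543), and 17 for krill oil against control and 10 for fish oil without the filter. An estimated correlation gave 0, 0 and 0, and fry, which does not compare a list with other genes, 0, 29 and 28. The interferon response, not called with all arrays and the filter, was called as lower in krill oil against control without the filter (-0.41, adjusted p = 0.00273), and in fish oil against control with array weights (-0.2, 0.000595) and without fish oil 5 (-0.16, 0.000156). The cause of these differences in lists was not tested.

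A gene's sign was counted as reversed only where the main fit or the alternative called it, and such reversals were few. Gene signs that changed with no call in either fit were counted apart. Under the alternatives set beforehand there were 10 of these in fish oil against control, 1 in krill oil against control and 5 in krill oil against fish oil. In the fits chosen after the data were seen there were 17, 5 and 4. Under quantile scaling Atp6v0a1 was at 1.10 in krill oil against control. With the mean of probe sets, Scd1 was at -1.0 against control and -0.77 against fish oil, as its probe sets differ in sign. With the pyruvate carboxylase covariate, krill oil against control gave -0.46 for Mtm1, -1.13 for Zfp982, -1.69 for Gm3715, 0.27 for G6pc, 0.15 for Ppargc1a, 0.04 for Abcg5 and a median of 0.04 for amino acid breakdown. Krill oil against fish oil gave -0.54 for Gm3715, and for amino acid breakdown a median of -0.09 with camera's direction up. Among named genes under the alternatives set beforehand, krill oil against control kept direction and side of the threshold in 713 values, lost the call in 10, gained it in 2 and reversed in 2. Krill oil against fish oil kept them in 519, lost the call in 2, gained it in 3 and reversed in 1. None of the 9 values from the covariate passed, and the cause was not tested. All 5 lists lower in krill oil against control lost their call with this covariate (adjusted p from 0.126 to 0.984), as did all 4 lower lists in krill oil against fish oil (0.0506 to 0.89). The 6 higher lists passed with it in both comparisons, with medians of 0.51 for complex I and 0.22 for the cytosolic ribosome against control, and 0.38 for ATP synthase and 0.25 for the cytosolic ribosome against fish oil. In krill oil against control, the beta-actin covariate ended the calls of cholesterol synthesis (-0.38, adjusted p = 0.124), fatty acid synthesis (-0.52, 0.175), gluconeogenesis (-0.33, 0.124) and amino acid breakdown (-0.37, 0.0678). In krill oil against fish oil it ended that of amino acid breakdown (-0.35, 0.083), while cholesterol synthesis stayed called (-0.55, 0.00125). Gluconeogenesis also lost its call with a stricter filter (0.103) and with the replicate number as a block (0.0567), a number that did not pair mice.

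The correlation of the fish oil and krill oil effects was 0.366 under quantile scaling, 0.386 without the filter, 0.04 with controls 4 to 7 for fish oil and 1 to 3 for krill oil, and -0.10 without fish oil 5, which reversed it; the cause was not tested. Genes of modest size that crossed the threshold in krill oil against control included G6pc (adjusted p = 0.0601 without the filter, 0.245 with median centring), Ppargc1a (0.226 under quantile scaling), Abcg5 (0.238 with median centring), and Hbb-b2 (0.0731) and Cybb (0.0665) with the mean of probe sets. Larger changes lost their call with the pyruvate carboxylase covariate, among them Fads1 (-0.65, adjusted p = 0.441), Fads2 (-0.78, 0.328), Fasn (-0.35, 0.738), Ppara (-1.16, 0.159) and Cyp7a1 (1.21, 0.188). In the fits chosen after the data were seen, named genes in this comparison kept direction and side of the threshold in 144 values. They lost the call in 66, gained it in 1 and reversed in 6. Signal near background limits the dimmest genes, since detection calls were not used here.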

Other observations

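Of the 2 hypotheses tested in this part, the test on the probe sets of a gene was chosen after the result was seen, and the test on gene length was set beforehand. Enzymes that detoxify foreign compounds went both ways in krill oil against control, with 9 genes higher and 8 lower of 25, and the list did not pass (adjusted p = 0.641). Cyp2c55, a P450 enzyme that oxidises fatty acids, rose by 1.84 ± 0.22, and Cyp1a2, of caffeine and arylamine metabolism, fell by 2.20 ± 0.30. Genes of glutathione metabolism also divided, with 6 higher and 10 lower of 30 (adjusted p = 0.959). Gpx4, which reduces lipid peroxides, rose by 1.33 ± 0.20, and Gstm1, a conjugating transferase, fell by 2.96 ± 0.38 (adjusted p = 3.99e-06). Rxra, the partner of PPAR-alpha and other nuclear receptors, fell by 1.90 ± 0.27 in the list of retinoid metabolism, where 2 genes were higher and 7 lower of 20 (adjusted p = 0.594, with a median of 0.06 and a mean of -0.29). Pltp, which transfers phospholipids between lipoproteins, fell by 2.67 ± 0.31 in a list with 5 higher and 7 lower of 23 (adjusted p = 0.959).

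Short genes could be favoured by RNA that is short, and the 20% of genes with the shortest span on the genome had a median log2 difference of 0.17 in krill oil against control and 0.257 in fish oil mouse 5 against its diet mates. The 6 respiratory chain, ribosome and proteasome lists had a mean of medians of 0.561. Groups of genes matched on span and brightness, 10000 of them, had a median of 0.236, with 95% between 0.108 and 0.356, so the lists lay at percentile 100. The lists had been called as higher in these same data, so a high percentile was likely beforehand. The matched groups held unrelated genes, while the lists had estimated correlations from 0.23 to 0.357, so that range is too narrow for them. The matched groups rose less than the lists, and no conclusion is drawn from the percentile. Span on the genome is not transcript length, which was not at hand, so a bias of transcript length stays open.

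If krill oil changed the amount of whole transcripts, probe sets of one gene should move together. Of 1972 genes with at least 2 called probe sets in krill oil against control, 220 (11.2%) were called in both directions. At an adjusted p under 0.001 the share was 2.7%, 19 of 696, so false calls may make up much of the 11.2%, and the test leaves open whether the pattern is one of whole-gene amounts. In krill oil against fish oil the shares were 7.8% (141 of 1813) and 2.1% (12 of 580).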
